A study of Saccharomyces cerevisiae with 63 samples.

How the data were processed

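Polyadenylated RNA was measured in 63 libraries of diploid budding yeast of the SK1 background, in which the promoter of the meiotic inducer gene IME1 had been replaced by a copper-inducible one. The libraries came from 3 strains (a control strain called WT here, an ime4 mutant and a pho92 mutant) at 0, 2, 3, 5, 6, 7 and 9 h in sporulation medium, which held 0.3% potassium acetate. Copper sulfate was added to 50 µM at 2 h. Each of the 21 combinations of strain and time had 3 libraries, which are biological replicates per the labels. Libraries were made from 500 ng of total RNA with a stranded TruSeq kit and sequenced as 50-nt single reads on an Illumina HiSeq instrument, per the labels' protocols.

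Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, aligned with TopHat2 2.0.14 and Bowtie, counted with HTSeq 0.6.1 and compared with DESeq2 1.22.1 in R 3.5.1. The strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here, nor is the genome build. Genes that overlap on opposite strands, and close paralogs such as the A and B copies of ribosomal protein genes or the enolase genes, may therefore share reads, and their separate values are uncertain. The deposited table held 1 raw read count per gene and library, whole numbers per the file headers, for 6088 genes. It also held a normalized signal that the authors made by dividing each count by 1 size factor per library, between 0.34 and 1.87, and a second deposited signal divided by gene length in kb. The deposited log2 fold changes, p-values and adjusted p-values of each mutant against WT at each time came from the authors' DESeq2 comparison. All fits below started from the raw counts. From the authors' comparison only the numbers of genes called, higher, lower and without an adjusted p-value were taken. The normalized signals were not used further.

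Gene identifiers of 5575 genes matched locus tags of the R64 reference annotation, from which names were taken, and 513 did not match and kept the name in the table, or the identifier where it had none. The S288C start positions in the table equalled those of R64 for 99.93% of the matched genes, so positions are given on R64. The table held 0 mitochondrially encoded genes. Total counts per library lay between 12826747 and 33048881 (median 16834032). Over genes with more than 20 counts in a pair of replicate libraries, counts differed by more than counting error (chi-square per degree of freedom of 9.46 to 652.19 between pairs), so over the sum of these genes the spread between replicates exceeded that of depth.

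Differential expression was tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were removed with filterByExpr by group (minimum count 10), which left 5822 genes and removed 266. Trimmed mean of M-values (TMM) factors scaled the libraries. A single quasi-likelihood (QL) model with 1 mean per group was fitted to all 63 libraries (common biological coefficient of variation 0.184, 42 residual degrees of freedom). Contrasts were WT at 2 h against 0 h, WT at 3, 6 and 9 h against 2 h, each mutant against WT at each of the 7 times and over the mean of 3, 5, 6, 7 and 9 h, and ime4 against pho92 over the same mean. A further F test of 6 contrasts per mutant asked whether its difference from WT varied over the times. Adjusted p is that of Benjamini and Hochberg (BH) over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are given as CPM on the TMM-scaled library size with the SD of 3 libraries, and fold changes on the log2 scale with their standard error (SE) from the edgeR fit.

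Named genes were chosen by a rule. IME4, PHO92 and IME1 were always taken. The 5 largest rises and 5 largest falls were taken for WT at 3 h and 9 h against 2 h, and the 8 largest in each direction for the means over 3 to 9 h. These had to be called, to reach a mean of 10 CPM in 1 group and, for the mutants, to have the same sign at all 5 times, and unnamed open reading frames were skipped. Up to 4 members with the smallest adjusted p were taken from each list described. The pairs of list and contrast that are described were picked after the list results had been seen, and genes outside the rule are named as such.

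The gene lists covered the m6A methyltransferase complex, meiotic entry regulators, double-strand break formation and chromosome axis, strand exchange and crossover formation, DNA replication, middle meiotic (Ndt80-dependent) genes, late spore wall genes, ribosome biogenesis, cytosolic ribosomal proteins, acetate use with the glyoxylate cycle and gluconeogenesis, the respiratory chain and ATP synthase, phosphate-responsive genes, copper-responsive genes, stress and trehalose or glycogen genes, haploid and mating genes, mitotic G1 and cell separation genes, auxotrophy markers, and the neighbours of IME4 and PHO92. These 18 lists were tested in the 21 contrasts with camera (inter-gene correlation 0.01), which compares a list with all other genes, with BH adjustment within each of 4 families (WT course, ime4, pho92, and ime4 against pho92). The test was repeated with an estimated correlation and with fry.

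The stage of a library was defined as the time on the linearly interpolated course of WT means, on a grid of 0.1 h, at which its log2 CPM (prior count 2) had the highest Pearson correlation. It used 4094 genes whose WT means spanned at least 2 log2 units, without IME4 and PHO92. Each WT library was staged against the means of the other WT replicates. The mean stage over 3 to 9 h was compared between strains with a two-sided exact permutation test on 3 values per strain, whose smallest possible p is 0.1. Stages were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

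The steps were tested on simulated data. With counts drawn for 5805 genes, of which 50 per fold size were changed, the comparison of ime4 with WT at 5 h called 8% of the changes of 1.25-fold, 42% of 1.5-fold, 84% of 2-fold and 100% of 4-fold, and 11 unchanged genes. For the mean of 3 to 9 h in ime4 these shares were 60%, 94%, 100% and 100%, with 18 unchanged genes called. For pho92, simulated with no change, 0 genes were called. The simulated changes were few and equally often up and down, whereas 82.4% of the measured genes were called in ime4 against WT at 7 h. Scaling under such broad changes was not tested. Of the 18 lists, the 1 shifted list was called and 0 others. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called wrongly. A simulated stage difference of −1.5 h in ime4 was recovered as −1.5 h, and a difference of 0 h in pho92 as 0.007 h. These libraries followed the interpolated WT course at a constant lag. Stages of mutants that leave this course, or whose lag varies with time, were not tested.

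The labels do not say whether equal replicate numbers share a day or a culture. Residuals of libraries with the same number had a correlation over 0.1 in every pair for WT at 3 h against 2 h (0.12 to 0.18), for pho92 against WT at 5 h (0.16 to 0.69) and at 6 h (0.23 to 0.58), and not for the other 18 contrasts. No block was used, and a fit with the replicate number as a block was run as an alternative. Other alternatives were DESeq2 1.42.0 with its own size factors, RLE factors, total counts only, no filter on low counts, a fit to the compared libraries only, and leaving out each replicate series of a strain in turn. Other gene sets, Spearman correlation and total-count scaling were tried for the stages. A fit without the libraries numbered 1 and a fit without the genes between MAT and HMR on chromosome III were chosen after seeing the data. DNA copy number and m6A itself were not analysed here.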

Results

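Transcript counts were obtained for 3 strains of diploid SK1 yeast, WT, ime4 and pho92, during a course of meiosis. IME4 encodes the catalytic subunit of the mRNA m6A methyltransferase, PHO92 encodes a YTH-domain protein that binds m6A, and IME1 encodes the transcription factor that starts the meiotic programme. Cells were moved to sporulation medium at 0 h, copper was added at 2 h to act on the copper-inducible promoter of IME1, and RNA was taken at 0, 2, 3, 5, 6, 7 and 9 h. Each strain and time had 3 biological replicates, 63 libraries in all, with total counts of 12826747 to 33048881. The 100 most abundant genes held 26.46% of the counts in WT at 3 h and 56.21% at 7 h, against 25.49% in ime4 and 39.95% in pho92 at 7 h.

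The deleted genes were near 0 in their own mutants. IME4 (YGL192W, chromosome VII, 142246 to 144048 on R64) had 0 to 2.37 CPM in the 21 ime4 libraries and 37.4 to 365 CPM in the 21 WT libraries. In WT its mean was 48.6 ± 9.49 CPM at 0 h, 146 ± 9.36 at 2 h, 342 ± 20 at 3 h and 42.4 ± 6.48 at 9 h (SD, n = 3). PHO92 (YDR374C, chromosome IV, 1223474 to 1224394) had 0 to 4.27 CPM in the 21 pho92 libraries. In WT its mean was 10.9 CPM at 0 h, 155 at 2 h, 1090 at 3 h, 2140 at 6 h and 459 at 9 h. Over 3 to 9 h the log2 fold change was −9.53 (SE 0.14) for IME4 in ime4 and −11.18 (SE 0.33) for PHO92 in pho92. PHO92 in ime4 stood at −0.30 (SE 0.20, adjusted p = 0.173) over 3 to 9 h, with 0.33 when only total counts scaled the libraries and −0.28 (adjusted p = 0.00206) in a fit to the compared libraries alone. This mean joins opposite changes. At 6 h PHO92 had 859 ± 152 CPM in ime4 against 2140 ± 106 in WT (−1.32, SE 0.46, adjusted p = 0.0091), a call lost with total counts only (−0.16, adjusted p = 0.743), and at 9 h 1730 ± 105 against 459 ± 44.8 CPM (1.92, SE 0.47, adjusted p = 0.000275). At 3, 5 and 7 h it stood at −0.59, −0.80 and −0.71 (adjusted p = 0.338, 0.142 and 0.142), which were called in fits to the compared libraries alone (adjusted p = 0.00353, 0.00469 and 0.0276), and at 7 h at 1.04 with total counts only (adjusted p = 0.0338). PHO92 at single times was picked after its values were seen. IME4 was lower in pho92 over 3 to 9 h by −0.31 (SE 0.08, adjusted p = 0.00106), a call that was lost with total counts only (0.00, adjusted p = 0.991).

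IME1 (YJR094C, chromosome X, 604569 to 605651) was already abundant before copper, with 2210 ± 571 CPM at 0 h and 3430 ± 59.8 CPM at 2 h in WT (SD, n = 3), a rise of 0.63 (log2, SE 0.25, adjusted p = 0.0298). This call was lost without WT replicate 2 (0.63, adjusted p = 0.131) and without WT replicate 3 (0.52, adjusted p = 0.19). From 2 to 3 h the change was −0.33 (SE 0.25, adjusted p = 0.251), or 0.03 with total counts only. By 9 h IME1 had fallen to 519 ± 59.8 CPM in WT (−2.72 against 2 h, SE 0.27). In ime4 IME1 had 1180 ± 185 CPM at 0 h, below the WT mean, and 4320 ± 295 CPM at 2 h, above it. It stayed high in ime4, at 4290 ± 596 CPM at 6 h and 3680 ± 400 at 7 h, against 2050 ± 387 and 964 ± 106 in WT. The difference was −0.22 (adjusted p = 0.542) at 3 h, with 0.00 without WT replicate 1, and −0.10 (adjusted p = 0.762) at 5 h, with 0.20 under total counts only. It was 1.06 (SE 0.25, adjusted p = 0.000241) at 6 h, 1.93 (SE 0.26) at 7 h and 1.79 (SE 0.26) at 9 h. Over 3 to 9 h IME1 was higher in ime4 by 0.89 (SE 0.11, adjusted p = 1.3e-09). In pho92 it differed from WT by 0.12 (SE 0.11, adjusted p = 0.371), which became 0.44 (adjusted p = 0.00415) with total counts only and −0.02 without pho92 replicate 3.

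**Figure D1:**
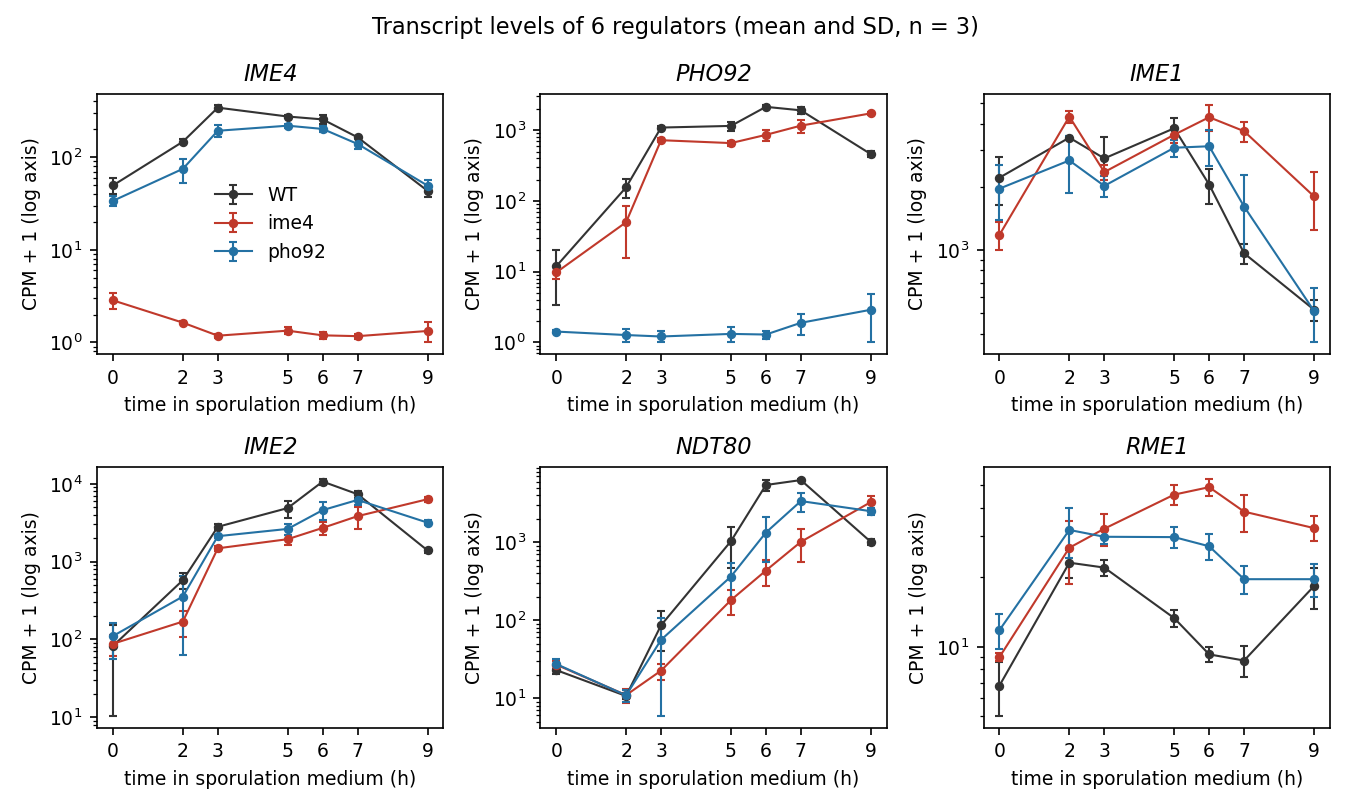
Transcript levels (CPM plus 1, log axis) of IME4, PHO92, IME1, IME2, NDT80 and RME1 against time in sporulation medium (h) in WT, ime4 and pho92; points are means and bars the SD of 3 libraries. NDT80 reached 6270 CPM at 7 h in WT, 1010 in ime4 and 3370 in pho92, and RME1 stood at 44.5 CPM in ime4 against 12.3 in WT at 5 h.

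The WT course shows which transcripts accompany each step of the programme, and the first contrast, 2 h against 0 h, covers the time before copper. Recombination genes rose strongly. REC8, the meiotic cohesin subunit, rose by 6.26 (log2, SE 0.54), SPO11, which makes the double-strand breaks, by 3.61 (SE 0.35), and HOP2, needed for homologue pairing, by 7.88 (SE 0.65; n = 3). All 12 genes of double-strand break formation and the chromosome axis rose (median 4.39; 12 adjusted over the list alone, camera adjusted p = 7.15e-10, and adjusted p = 0.324 with an estimated correlation). Of the 16 genes of strand exchange and crossover formation 15 rose (median 4.11; 15 adjusted over the list alone, camera adjusted p = 2.9e-11, and adjusted p = 0.324 with an estimated correlation).

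All 6 genes of the m6A methyltransferase complex rose between 0 and 2 h in WT (median 1.41; 6 adjusted over the list alone, camera adjusted p = 0.000267, and adjusted p = 0.324 with an estimated correlation). IME4 rose by 1.58 (SE 0.19), VIR1 by 1.57 (SE 0.21), KAR4 by 1.25 (SE 0.15) and MUM2 by 1.09 (SE 0.12). Of 31 genes of the respiratory chain and ATP synthase 28 fell (median −1.16; 28 adjusted over the list alone, camera adjusted p = 7.94e-11, and adjusted p = 0.324 with an estimated correlation), with CYC1 at −2.97 (SE 0.26) and COX5A at −1.78 (SE 0.14). Among 8 copper-responsive genes 5 fell and 1 rose (7 adjusted over the list alone, camera adjusted p = 0.173), with the copper transporter gene CTR1 at −2.57 (SE 0.33) and the reductase gene FRE7 at −2.01 (SE 0.21). In all, 1547 genes rose and 1767 fell. Scaling by total counts shifted the median of all genes by 0.22 and gave 1971 higher and 1179 lower, so changes here are relative to the TMM reference.

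In the hour after copper, from 2 to 3 h in WT, DNA replication genes rose and ribosomal protein, gluconeogenic and stress genes fell. All 19 DNA replication genes rose (median 2.44; 19 adjusted over the list alone, camera adjusted p = 2.07e-11, and adjusted p = 0.324 with an estimated correlation), among them the thymidylate synthase gene CDC21 by 3.25 (SE 0.23) and the polymerase gene POL3 by 1.60 (SE 0.14; n = 3). The largest rises were LDS2 (5.23, SE 0.69), RNP1 (4.45, SE 0.53), the S-phase cyclin gene CLB6 (4.43, SE 0.66), REC114 (3.96, SE 0.46) and the splicing regulator MER1 (3.82, SE 0.42), where LDS2 was 5.91 and CLB6 5.24 without WT replicate 1. The largest falls were in the glycolytic genes ENO1 (−6.08, SE 0.43), FBA1 (−5.66, SE 0.53) and PGK1 (−5.48, SE 0.49) and in SIP18 (−5.63, SE 0.47) and FAT3 (−5.46, SE 0.50), where reads of ENO1 may be shared with its paralog. IME4 rose by 1.23 (SE 0.18) and PHO92 by 2.81 (SE 0.49).

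Of 113 cytosolic ribosomal protein genes 112 fell from 2 to 3 h in WT (median −2.81; 113 called adjusted over the list alone, camera adjusted p = 2.42e-33, and adjusted p = 0.324 with an estimated correlation). RPS26A fell by 3.43 (SE 0.27), and the exception, RPL15B, rose by 1.67 (SE 0.13), although paired copies of these genes may share reads. Of 18 genes of acetate use and gluconeogenesis 17 fell (median −1.66; 17 adjusted over the list alone, camera adjusted p = 7.46e-07, and adjusted p = 0.324 with an estimated correlation), with FBP1 at −3.78 (SE 0.24) and PCK1 at −3.56 (SE 0.34). Of 22 stress and trehalose or glycogen genes 17 fell and 1 rose (median −1.64; 18 adjusted over the list alone, camera adjusted p = 5.27e-08, and adjusted p = 0.324 with an estimated correlation), with GPH1 at −4.96 (SE 0.41) and HSP12 at −4.74 (SE 0.36). Altogether 2112 genes rose and 1705 fell. Under total-count scaling the median of all genes shifted by 0.36, and 2909 were higher and 1054 lower.

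Middle and late meiotic genes rose in WT at 6 h against 2 h. NDT80, the transcription factor of the middle programme (YHR124W, chromosome VIII, 356561 to 358444), rose from 9.65 ± 0.901 to 5420 ± 884 CPM (log2 9.14, SE 0.59, n = 3). Of 35 middle meiotic genes 34 rose (median 8.92; 34 adjusted over the list alone, camera adjusted p = 1.31e-13, and adjusted p = 0.324 with an estimated correlation), including SPR28 by 10.11 (SE 0.65) and ADY3 by 6.82 (SE 0.41). Of 13 late spore wall genes 12 rose and 1 fell (median 8.57; 13 adjusted over the list alone, camera adjusted p = 7.62e-05, and adjusted p = 0.324 with an estimated correlation), including LDS1 by 11.56 (SE 0.87, or 12.21 without WT replicate 1) and the chitin deacetylase gene CDA1 by 8.57 (SE 0.59). In total 2283 genes rose and 2413 fell. If total counts alone scaled the libraries, the median shifted by −0.75, and 1381 were higher and 3463 lower, while RLE factors gave 2362 and 2334.

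At 9 h against 2 h in WT, the hexose transporter gene HXT10 (12.74, SE 1.20), the sporulation gene SPS4 (12.59, SE 1.01), GAT4 (11.77, SE 1.00), GAT3 (11.23, SE 0.74) and SPR2 (10.56, SE 1.00) had the largest rises. NCA3 (−7.15, SE 0.54), ISF1 (−7.03, SE 0.64), NRS1 (−6.30, SE 0.42), YGP1 (−6.01, SE 0.28) and the fatty acid desaturase gene OLE1 (−5.80, SE 0.76) had the largest falls. Of 28 ribosome biogenesis genes 20 rose and 1 fell (median 1.28; 21 adjusted over the list alone, camera adjusted p = 0.00527, and adjusted p = 0.717 with an estimated correlation), with DRS1 at 2.98 (SE 0.38) and UTP20 at 2.35 (SE 0.23). Of 18 mitotic G1 and cell separation genes 14 fell (median −1.74; 14 adjusted over the list alone, camera adjusted p = 0.00236, and adjusted p = 0.324 with an estimated correlation), with DSE2 at −5.40 (SE 0.30) and ASH1 at −2.90 (SE 0.22). IME4 fell by 1.78 (SE 0.19), while PHO92 stood above its 2 h level by 1.57 (SE 0.46, adjusted p = 0.00228), a call lost without WT replicate 3 (1.23, adjusted p = 0.0667). In total 2324 genes rose and 2225 fell. With total counts only the median shifted by −0.43, and 1588 were higher and 2806 lower.

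The comparison of ime4 with WT asks what loss of the methyltransferase does to the course. At 0 h 9 genes were higher and 6 lower in ime4, IME4 among the latter. The glycerophosphoinositol permease gene GIT1 was lower by −1.73 (SE 0.27, adjusted p = 0.000165, n = 3; adjusted p = 0.846 in a fit to the 6 compared libraries alone, and −2.36 without the libraries numbered 1). Of 20 phosphate-responsive genes GIT1 alone was called (2 adjusted over the list alone, median −0.31, camera adjusted p = 4.59e-08, and adjusted p = 0.0843 with an estimated correlation). The count of 15 genes depended on single libraries. It was 70 without WT replicate 1, 63 without ime4 replicate 1, 9 without ime4 replicate 2, 205 without any library numbered 1, 26 with DESeq2 and 1 in a fit to the compared libraries alone. Total counts gave 14 higher and 4 lower.

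At 2 h, still before copper, recombination and replication genes were lower in ime4, and the G1 cyclin genes CLN1 and CLN2 were higher. MER1 was lower by −3.00 (SE 0.53), the recombination gene ECM11 by −3.01 (SE 0.50), MSH4 by −2.13 (SE 0.38) and the ribonucleotide reductase gene RNR1 by −2.28 (SE 0.35; n = 3). Without the libraries numbered 1, MER1 stood at −2.06, ECM11 at −2.01 and MSH4 at −1.44, and without ime4 replicate 3 at −4.64, −4.08 and −2.81, while ECM11 was −2.42 without WT replicate 1. CLN1 was higher by 1.41 (SE 0.19) and CLN2 by 1.12 (SE 0.23). All 12 genes of break formation and the axis were lower (median −1.97; 12 adjusted over the list alone, camera adjusted p = 3.2e-15, and adjusted p = 0.162 with an estimated correlation), as were all 16 of strand exchange (median −1.82; 16 adjusted over the list alone, camera adjusted p = 1.06e-19, and adjusted p = 0.15 with an estimated correlation). Of 19 DNA replication genes 13 were lower (median −0.94; 14 adjusted over the list alone, camera adjusted p = 6.64e-11, and adjusted p = 0.383 with an estimated correlation). Of 18 mitotic G1 and cell separation genes 6 were higher and 1 lower (median 0.51; 14 adjusted over the list alone, camera adjusted p = 4.46e-05, and adjusted p = 0.15 with an estimated correlation).

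In the m6A complex list 5 of 6 genes were lower in ime4 at 2 h (5 adjusted over the list alone, median −0.78, camera adjusted p = 1.38e-21, and adjusted p = 0.000134 with an estimated correlation). These were IME4 itself, SLZ1 (−1.73, SE 0.31), MUM2 (−0.77, SE 0.12), VIR1 (−0.80, SE 0.21, outside the naming rule) and KAR4 (−0.66, SE 0.15, adjusted p = 0.00168). KAR4 was not called with total counts only (adjusted p = 0.0799) or without the libraries numbered 1 (−0.53, adjusted p = 0.0878). This list at 0, 2 and 3 h in ime4, which contains the deleted gene, gave the 3 of 97 list calls that hold with an estimated correlation (adjusted p = 0.0121, 0.000134 and 0.0121). The list was not tested without IME4, so these 3 calls may rest on the deletion itself. In all, 330 genes were higher and 390 lower at 2 h. The count of 720 was 433 without WT replicate 1, 381 without WT replicate 2, 377 without ime4 replicate 2 and 457 without the libraries numbered 1, where 9 break and axis, 12 strand exchange and 7 DNA replication genes were lower. Under total-count scaling the median shifted by 0.12, and 450 were higher and 167 lower.

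At 3 h ribosome biogenesis genes were higher in ime4 than in WT. DBP3 was higher by 1.47 (SE 0.36) and RRP5 by 1.38 (SE 0.33; n = 3). Of 28 ribosome biogenesis genes 20 were higher (21 adjusted over the list alone, median 1.05, camera adjusted p = 1.82e-06, and adjusted p = 0.955 with an estimated correlation). In total 859 genes were higher and 923 lower. The count of 1782 was 1019 without WT replicate 2 and 1046 without ime4 replicate 2, and with total counts only the median shifted by 0.12, with 956 higher and 357 lower.

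Middle genes were lower in ime4 at 5 and 6 h, and late genes at 6 h. NDT80 had 432 ± 156 CPM in ime4 against 5420 ± 884 in WT at 6 h (SD, n = 3; its time points other than the WT contrast were picked after the values were seen). The B-type cyclin gene CLB4 was lower at 6 h by −5.95 (SE 0.50), MIP6 by −6.09 (SE 0.55) and the spindle pole body gene SPO21 by −5.94 (SE 0.54). At 5 h 31 of 35 middle genes were lower and 1 higher (median −3.67; 32 adjusted over the list alone, camera adjusted p = 1.99e-13, and adjusted p = 0.88 with an estimated correlation). Of the 35 genes 33 were lower and 1 higher at 6 h (median −5.50; 34 adjusted over the list alone, camera adjusted p = 6.64e-11, and adjusted p = 0.88 with an estimated correlation). Of 13 late spore wall genes 11 were lower and 1 higher (median −4.65; 12 adjusted over the list alone, camera adjusted p = 0.00113, and adjusted p = 0.88 with an estimated correlation), with CDA1 at −5.57 (SE 0.51) and SPO73 at −4.65 (SE 0.34). At 5 h 1365 genes were higher and 1514 lower, and at 6 h 2536 and 2009. When total counts alone scaled the libraries, the median shifted by 0.30 at 5 h (1974 higher, 698 lower) and 1.15 at 6 h (4258 higher, 926 lower).

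By 9 h strand exchange genes were higher and ribosomal protein genes were lower in ime4. NDT80 in ime4 reached 3270 ± 608 CPM at 9 h, and the kinase gene IME2 6340 ± 413 CPM, against a WT peak of 10700 ± 897 CPM for IME2 at 6 h (SD, n = 3; IME2 was picked after its values were seen). All 16 strand exchange genes were higher in ime4 at 9 h (median 1.64; 16 adjusted over the list alone, camera adjusted p = 0.117), with MEI5 at 3.86 (SE 0.50) and MLH3 at 1.86 (SE 0.17). Of 113 ribosomal protein genes 110 were lower and 1 higher (median −3.33; 111 adjusted over the list alone, camera adjusted p = 1.67e-23, and adjusted p = 0.88 with an estimated correlation), with RPS22B at −5.40 (SE 0.31) and RPS1A at −4.30 (SE 0.28). At 7 h 2613 genes were higher and 2184 lower, and at 9 h 2733 and 1938. With total counts only the median shifted by 1.77 at 7 h (4490 higher, 713 lower) and −0.16 at 9 h (2402 higher, 2051 lower). RLE factors gave 2373 higher and 2408 lower at 7 h, and a fit to the compared libraries alone gave 2183 and 2208 at 9 h.

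Over the mean of 3 to 9 h, the largest rises in ime4 against WT were VPS73 (3.17, SE 0.12), GRE2 (3.13, SE 0.17), the G1 transcription factor gene MSA2 (2.91, SE 0.13), the amino acid permease gene GAP1 (2.87, SE 0.24), the bud-neck kinase gene GIN4 (2.86, SE 0.10), DET1 (2.85, SE 0.09), AFB1 (2.80, SE 0.15) and YPS3 (2.73, SE 0.10). Apart from IME4, the largest falls were HXT10 (−4.39, SE 0.38), SPS4 (−4.23, SE 0.32), the chitinase gene CTS2 (−4.07, SE 0.29), PIR5 (−3.77, SE 0.28), EMI2 (−2.86, SE 0.19), GAT3 (−2.62, SE 0.22) and the spore wall gene DIT2 (−2.61, SE 0.17). Each had the same sign at all 5 times (3 libraries per strain and time). The 18 meiotic entry regulators went both ways, 7 higher and 8 lower (17 adjusted over the list alone, camera adjusted p = 0.898). RME1 was higher by 1.62 (SE 0.09), UME6 by 1.33 (SE 0.07) and RIM21 by 0.56 (SE 0.04), while MCK1 was lower by −0.69 (SE 0.05), a call lost with total counts only (−0.05, adjusted p = 0.292).

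Of the 18 mitotic G1 and cell separation genes 10 were higher and 5 lower in ime4 over 3 to 9 h (15 adjusted over the list alone, camera adjusted p = 0.0905), with CLN1 at 1.35 (SE 0.09), CLN2 at 1.34 (SE 0.10) and ASH1 at 1.21 (SE 0.09). Of 9 auxotrophy markers 7 were higher and 1 lower (8 adjusted over the list alone, camera adjusted p = 0.291), with TRP1 at 1.24 (SE 0.08), URA3 at 0.87 (SE 0.12), LYS5 at 0.74 (SE 0.09) and LYS2 at −0.70 (SE 0.10; −0.06 and adjusted p = 0.471 with total counts only). Of the 7 neighbours of IME4 and PHO92 3 were higher and 3 lower (6 adjusted over the list alone, camera adjusted p = 0.908). BCS1 stood at 0.66 (SE 0.07) and VPS74 at 0.39 (SE 0.07), while HOS2 at −0.54 (SE 0.06) and COX13 at −0.43 (SE 0.07) turned to 0.10 and 0.21 with total counts only. In total 2286 genes were higher and 2145 lower, 432 and 537 of them by at least 2-fold. Under total-count scaling the median shifted by 0.64, and 4378 were higher and 723 lower, while RLE factors gave 2070 and 2350.

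**Figure D2:**
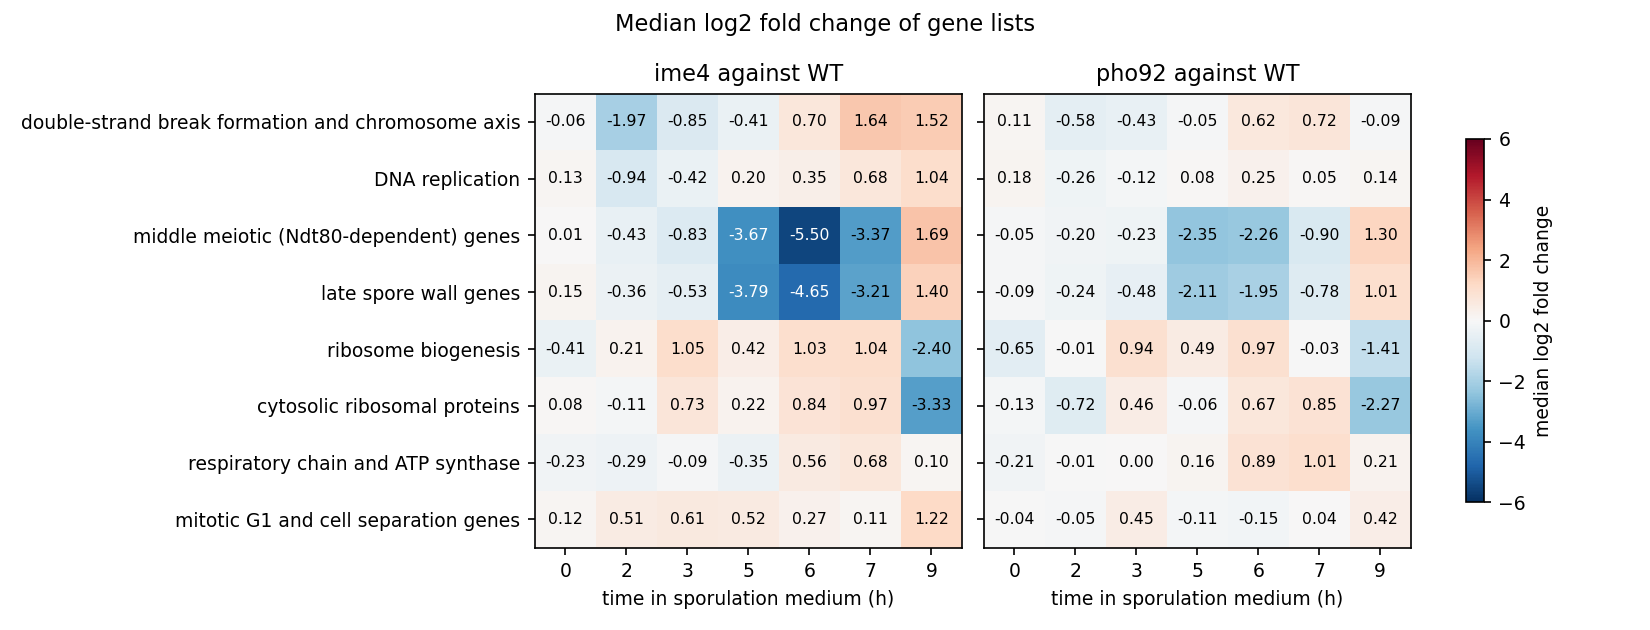
Median log2 fold change of 8 gene lists (vertical axis) in ime4 and pho92 against WT at each time in sporulation medium (h, horizontal axis), written in each cell and coloured from blue (lower in the mutant) to red (higher), with 3 libraries per strain and time. Middle meiotic genes stood at −5.50 in ime4 at 6 h and −2.35 in pho92 at 5 h, and cytosolic ribosomal proteins at −3.33 in ime4 and −2.27 in pho92 at 9 h.

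The pho92 strain, which lacks the m6A reader, was compared with WT. With TMM scaling, every pho92 library also had lower transcripts of 48 neighbouring chromosome III genes, described below (library medians of −1.195 to −0.365, log2 against WT). Effects of losing PHO92 and of these lower transcripts cannot be told apart in this design. This holds for the counts, lists and stages of pho92 and for its contrast with ime4. Already at 0 h 636 genes were higher and 416 lower. SSA4 was higher by 1.82 (SE 0.29), HSP12 by 1.43 (SE 0.31), HXK1 by 1.39 (SE 0.26) and HSP78 by 1.19 (SE 0.19; n = 3). Of 22 stress and trehalose or glycogen genes 8 were higher (median 0.35; 9 adjusted over the list alone, camera adjusted p = 0.0073, and adjusted p = 0.977 with an estimated correlation). Of 28 ribosome biogenesis genes 6 were lower (median −0.65; 7 adjusted over the list alone, camera adjusted p = 0.000273, and adjusted p = 0.977 with an estimated correlation), and 20 were lower without the libraries numbered 1. UTP22 stood at −1.01 (SE 0.28, adjusted p = 0.00624) and BFR2 at −1.19 (SE 0.36, adjusted p = 0.0134). Without WT replicate 2 their adjusted p was 0.414 and 0.404, without pho92 replicate 3 it was 0.0503 and 0.0972, and for BFR2 without WT replicate 3 it was 0.0539. The count of 1052 genes was 553 without WT replicate 2, and total counts gave 572 higher and 184 lower.

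A run of 48 neighbouring genes on chromosome III was lower in pho92 at 0 h. They lie between the mating-type locus MAT and the silent locus HMR, from TAF2 (start 201174) to YCR095W-A (end 289797) on R64. Of the 48 genes 40 were lower, with a median of −1.06, and 8 were not called. The nearest 26 genes outside the interval had a median of −0.04. The interval median was −0.92 at 2 h, −0.88 at 3 h, −0.85 at 5 h, −0.64 at 6 h, −0.65 at 7 h and −1.14 at 9 h, although with total counts only it was 0.21 at 6 h and 0.21 at 7 h, where that scaling moved the median of all genes by 0.85 and 0.84. In ime4 it was 0.05 at 0 h. The corepressor gene TUP1 stood at −1.19 and the mRNA decay gene PAT1 at −1.14 at 0 h in pho92. The interval was noticed, and these members picked, after the values were seen.

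**Figure D3:**
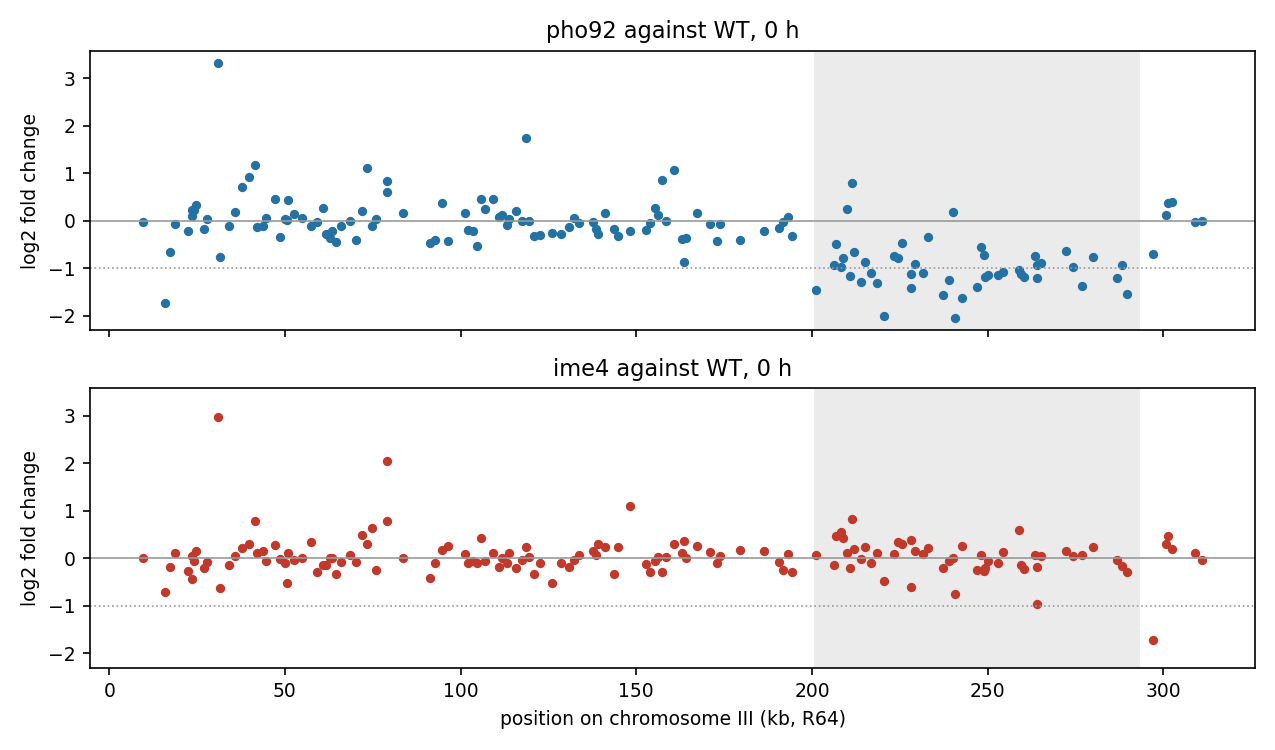
Log2 fold change against WT at 0 h (vertical axis) of genes by their position on chromosome III (kb, R64, horizontal axis) in pho92 (top) and ime4 (bottom); each point is a gene from 3 libraries per strain, the shaded span runs from MAT to HMR, and the dotted line marks −1. Genes in the span had a median of −1.06 in pho92 and 0.05 in ime4.

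At 2 h IME4 was lower in pho92 than in WT by −0.98 (SE 0.18, adjusted p = 0.000204, n = 3). In the m6A complex list 4 of 6 genes were lower (5 adjusted over the list alone, median −0.59, camera adjusted p = 2.9e-05, and adjusted p = 0.973 with an estimated correlation). Of these 4, MUM2, KAR4 and SLZ1 were not called with total counts only (adjusted p = 0.0615, 0.0822 and 0.101) or in a fit to the compared libraries alone (0.116, 0.0637 and 0.287), and SLZ1 (−0.89, SE 0.30) was not called with WT replicate 1, 2 or 3 or pho92 replicate 2 or 3 left out (adjusted p = 0.125, 0.139, 0.0644, 0.289 and 0.297) and stood at −1.85 without pho92 replicate 1 and −1.73 without the libraries numbered 1. Of 113 ribosomal protein genes 32 were lower (67 adjusted over the list alone, median −0.72, camera adjusted p = 5.44e-21, and adjusted p = 0.977 with an estimated correlation), but 3 were lower without the libraries numbered 1. RPS11B at −1.10 (SE 0.26) and RPL11A at −1.08 (SE 0.26) were not called without WT replicate 2 (adjusted p = 0.163 and 0.134) or in a fit to the compared libraries alone (0.0929 and 0.098), and RPL28 (−0.86, SE 0.21) and RPS13 (−0.83, SE 0.23) were not called in these settings (adjusted p = 0.123 and 0.198, then 0.133 and 0.15) or with total counts only (0.0641 and 0.0647). RPS13 was also not called without pho92 replicate 1 or 2 (adjusted p = 0.0802 and 0.0855) or without the libraries numbered 1 (0.0651). In total 493 genes were higher and 227 lower, or 572 and 72 with total counts only, 395 and 301 with RLE factors and 461 and 378 with DESeq2. The count of 720 was 224 without WT replicate 2, 410 without pho92 replicate 2, 388 without pho92 replicate 3 and 166 in a fit to the compared libraries alone.

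Ribosome biogenesis genes were higher in pho92 at 3 h, with RRP5 at 1.41 (SE 0.33), NOP4 at 1.27 (SE 0.26) and UTP4 at 1.25 (SE 0.29; n = 3). Of the 28 genes 16 were higher (24 adjusted over the list alone, median 0.94, camera adjusted p = 4e-08, and adjusted p = 0.977 with an estimated correlation). In total 597 genes were higher and 445 lower, or 643 and 159 with total counts only, 496 and 632 with RLE factors and 555 and 746 with DESeq2. The count of 1042 was 395 without WT replicate 2, 650 without pho92 replicate 2, 579 without pho92 replicate 3 and 2215 in a fit to the compared libraries alone.

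Middle genes were lower in pho92 at 5 h, and respiratory genes were higher at 6 h. At 5 h SPS22 was lower by −2.83 (SE 0.55), SPO21 by −2.64 (SE 0.47), the polo kinase gene CDC5 by −2.57 (SE 0.49) and CLB4 by −2.35 (SE 0.42; n = 3), of which CDC5 missed the threshold in a fit to the compared libraries alone (adjusted p = 0.0607). Without WT replicate 1 these 4 genes stood at −1.75, −1.68, −1.80 and −1.44, and without pho92 replicate 1 at −3.77, −3.58, −3.99 and −2.95, and CDC5 was −3.22 without the libraries numbered 1. The pho92 libraries of 5 h matched WT at 4.5, 4.1 and 2.6 h. Of 35 middle genes 31 were lower (median −2.35; 31 adjusted over the list alone, camera adjusted p = 4.89e-13, and adjusted p = 0.977 with an estimated correlation). At 6 h 24 of 31 respiratory chain and ATP synthase genes were higher (median 0.89; 24 adjusted over the list alone, camera adjusted p = 7.23e-07, and adjusted p = 0.977 with an estimated correlation), with ATP4 at 1.66 (SE 0.15), SDH1 at 1.62 (SE 0.19) and COX4 at 1.61 (SE 0.18). NDT80 reached 3370 ± 923 CPM at 7 h in pho92. At 5 h 1008 genes were higher and 950 lower, a count of 1958 that was 1209 without WT replicate 1, and at 6 h 2200 and 1919. If total counts alone scaled the libraries, the median shifted by 0.20 at 5 h (1377 higher, 484 lower) and 0.85 at 6 h (3965 higher, 795 lower). RLE factors gave 915 higher and 1089 lower at 5 h and 1976 and 2062 at 6 h.

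At 9 h 108 of 113 ribosomal protein genes were lower and 1 higher in pho92 (median −2.27; 109 adjusted over the list alone, camera adjusted p = 2.48e-40, and adjusted p = 0.977 with an estimated correlation). RPS16B was lower by −3.10 (SE 0.31) and RPL28 by −2.42 (SE 0.23; n = 3). At 7 h 2019 genes were higher and 1638 lower, and at 9 h 1884 and 1442. With total counts only the median shifted by 0.84 at 7 h (3908 higher, 416 lower) and −0.45 at 9 h (927 higher, 2546 lower). RLE factors gave 1777 higher and 1898 lower at 7 h.

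The largest rises in pho92 over 3 to 9 h were in the ammonium permease gene MEP2 (2.48, SE 0.26), VPS73 (2.27, SE 0.12), the glycine cleavage gene GCV1 (2.12, SE 0.19), MGA1 (2.11, SE 0.20), GAP1 (2.08, SE 0.24), GRE2 (2.01, SE 0.18), GDH1 (1.99, SE 0.27) and the acetyl-CoA synthetase gene ACS2 (1.98, SE 0.14). Apart from PHO92, the largest falls were RRT12 (−2.18, SE 0.27), CTR86 (−1.69, SE 0.12), CSM1 (−1.58, SE 0.09), FCY22 (−1.51, SE 0.15), ARO10 (−1.50, SE 0.17), BUD31 (−1.46, SE 0.12) and DIT2 (−1.35, SE 0.17). Of these, RRT12, CTR86, CSM1 and BUD31 lie in the interval between MAT and HMR, where 43 of 48 genes were lower over 3 to 9 h (median −0.88). FRQ1, the gene next to PHO92, was lower by −1.29 (SE 0.09).

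Of 18 genes of acetate use and gluconeogenesis 13 were higher and 2 lower in pho92 over 3 to 9 h (16 adjusted over the list alone, median 0.60, camera adjusted p = 0.0392, and adjusted p = 0.977 with an estimated correlation), with YAT2 at 1.34 (SE 0.15), IDP2 at 0.88 (SE 0.13) and MDH2 at 0.84 (SE 0.12). The 18 meiotic entry regulators split into 5 higher and 7 lower (13 adjusted over the list alone, camera adjusted p = 0.87), with RME1 at 0.94 (SE 0.09) and UME6 at 0.69 (SE 0.07). Of 20 phosphate-responsive genes 5 were higher and 8 lower (13 adjusted over the list alone, camera adjusted p = 0.787), with the kinase gene PHO85 at 0.51 (SE 0.07) and GDE1 at −0.47 (SE 0.09). Of the 7 neighbours of IME4 and PHO92 2 were higher and 2 lower (4 adjusted over the list alone, camera adjusted p = 0.705), and HOS2 at −0.17 (SE 0.06) turned to 0.13 with total counts only and was not called without WT replicate 2 (adjusted p = 0.0517). In total 1972 genes were higher and 1539 lower, 123 and 123 of them by at least 2-fold. Under total-count scaling the median shifted by 0.31 and 3755 were higher and 556 lower, while RLE factors gave 1593 and 1919 and DESeq2 1617 and 1941.

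The direct contrast of ime4 with pho92 over 3 to 9 h tested where the mutants differ. Lower in ime4 were SPR2 at −3.12 (SE 0.32), HXT10 at −2.78 (SE 0.36), SPR3 and SPS4 at −2.72 (SE 0.25 and 0.30), SMA1 at −2.69 (SE 0.26), the kinase gene SMK1 at −2.57 (SE 0.29) and PFS1 at −2.54 (SE 0.28; 3 libraries per strain and time). Without the libraries numbered 1 these 7 genes stood at −2.30 to −1.83 (SPR2 −2.30, HXT10 −1.95, SPR3 −2.06, SPS4 −1.94, SMA1 −2.01, SMK1 −1.83, PFS1 −1.84), and without pho92 replicate 1 SPR2, HXT10, SPS4, SMA1, SMK1 and PFS1 stood at −2.42, −2.10, −2.03, −2.07, −1.93 and −1.93. Apart from PHO92, higher in ime4 were REV1 (1.96, SE 0.09), SKG6 (1.85, SE 0.10), MSA2 (1.79, SE 0.12), SPL2 (1.78, SE 0.15), AHC2 (1.68, SE 0.05), ARE1 (1.61, SE 0.08) and GIN4 (1.57, SE 0.10). AHC2 and ARE1 lie between MAT and HMR, where 45 of 48 genes were higher in ime4 than in pho92 (median 1.02). IME1 was higher in ime4 by 0.77 (SE 0.11, adjusted p = 7.14e-08).

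Of 35 middle genes 34 were lower and 1 higher in ime4 than in pho92 (median −1.62; 35 adjusted over the list alone, camera adjusted p = 2.41e-08, and adjusted p = 0.675 with an estimated correlation). Of 22 stress and trehalose or glycogen genes 15 were lower and 2 higher (18 adjusted over the list alone, camera adjusted p = 0.0129, and adjusted p = 0.675 with an estimated correlation), with DDR2 at −2.31 (SE 0.25), HSP12 at −1.41 (SE 0.14), TPS1 at −0.68 (SE 0.07) and TSL1 at 0.94 (SE 0.08). Of 18 haploid and mating genes 7 were higher and 4 lower (11 adjusted over the list alone, camera adjusted p = 0.478), with SST2 at 0.74 (SE 0.07), the kinase gene FUS3 at 0.62 (SE 0.07), STE6 at 0.56 (SE 0.06) and GPA1 at −0.66 (SE 0.09). In total 1803 genes were higher and 2082 lower, 119 and 248 of them by at least 2-fold. If total counts alone scaled the libraries, the median shifted by 0.33, and 3326 were higher and 821 lower.

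The stage of a library, its best-matching time on the WT course, was earlier by value in both mutants, in a design that cannot reach a p of 0.05. Over 3 to 9 h the mean stage was 6.01 h in WT, 4.15 h in ime4 and 5.17 h in pho92. The difference from WT was −1.85 h (SE 0.174) in ime4 and −0.833 h (SE 0.268) in pho92 (n = 3 replicates per strain, two-sided exact permutation p = 0.1 for each, the smallest possible). This mean joins unlike times, since at 3 h the difference was −0.334 h in ime4 and −0.267 h in pho92, and from 5 to 9 h it lay between −2.5 and −2.066 h in ime4 and between −1.167 and −0.8 h in pho92. Libraries of ime4 matched WT at 2.73 h after 3 h, 2.6 h after 5 h, 3.97 h after 6 h and 6.47 h after 9 h, with no advance from 3 to 5 h. Those of pho92 matched 3.73 h after 5 h (SD 1.002, with replicates 1 to 3 at 4.5, 4.1 and 2.6 h, exact p = 0.2 against WT), 5.13 h after 6 h and 8.17 h after 9 h. At 5, 6 and 7 h the lowest correlation at the best match was 0.959, 0.955 and 0.946 in ime4. It was 0.965, 0.98 and 0.981 in pho92 and 0.991, 0.995 and 0.992 in WT, so the mutants matched the WT course less closely. The library numbered 1 alone stood latest in 6 of 6 pho92 groups from 2 to 9 h, in 5 of 6 WT groups and in 0 of 6 ime4 groups.

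**Figure D4:**
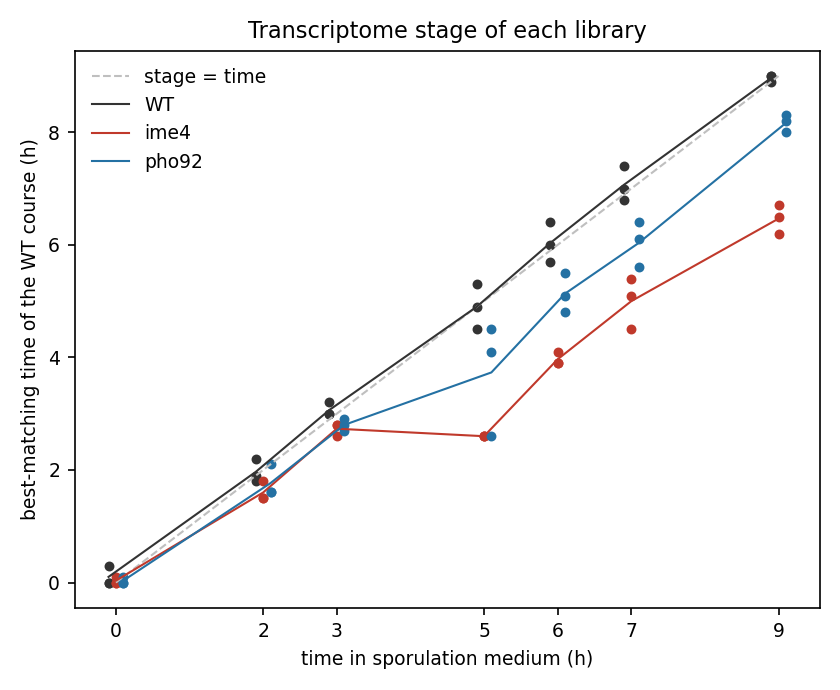
Best-matching time on the WT course (h, vertical axis) of each of the 63 libraries (points) against time in sporulation medium (h, horizontal axis), with lines through the means of 3 libraries of WT, ime4 and pho92; the dashed line marks a stage equal to the time. From 5 h on the means lay at 2.6 to 6.47 h in ime4 and 3.73 to 8.17 h in pho92.

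The difference from WT varied over the 7 times for 5605 of 5822 genes in ime4 and for 5272 in pho92 (edgeR F test, BH adjusted). NDT80 (adjusted p = 4.24e-11 in ime4 and 3.21e-05 in pho92) and IME1 (adjusted p = 2.76e-10 and 0.00698) were among them. The mutants' differences from WT over 3 to 9 h had a Pearson correlation of 0.765 across 5820 genes, which are not independent replicates. Both differences use the same WT libraries. Simulated data with no mutant effect and the same shared controls gave 0.529 (0.48 to 0.565 in 20 simulations), with a covariance of 0.00849 against 0.279 observed. In both mutants 1472 genes were higher, where independence would give 774.6, and 1260 were lower, where it would give 566.2, and 242 went in opposite directions. The 3 WT replicates could not be split into parts of at least 2 to give each mutant its own controls, so part of the excess in these gene counts may come from the shared controls. The gene counts and the covariance were taken with TMM scaling only. Total counts gave 4378 higher and 723 lower in ime4, and 3755 and 556 in pho92, so the overlap depends on the scaling too. For the covariance, to which shared controls add the same amount with or without effects, observed minus simulated was 0.2709.

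In the deposited table, the authors' DESeq2 comparison gave 55, 835, 1999, 2974, 4534, 4853 and 4736 genes at an adjusted p under 0.05 for ime4 at 0, 2, 3, 5, 6, 7 and 9 h, and 1351, 840, 1311, 2147, 4102, 3736 and 3381 for pho92. The counts from the edgeR QL fit were 15, 720, 1782, 2879, 4545, 4797 and 4671 for ime4 and 1052, 720, 1042, 1958, 4119, 3657 and 3326 for pho92. The deposited table held 6088 genes, and 5822 were tested here. It lacked an adjusted p for 237 genes in ime4 at 3 h and in pho92 at 0 h, and for 355 in pho92 at 5 h. The direction with more called genes differed for ime4 at 7 h (2400 higher and 2453 lower per the authors). It also differed for pho92 at 3 h (560 and 751), 5 h (978 and 1169), 6 h (2015 and 2087) and 7 h (1795 and 1941). In the other comparisons it was the same.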

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

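All tests of the explanations weighed here were chosen after the result was seen. The counts over other groupings of the libraries were planned.

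For 5605 genes in ime4 and 5272 genes in pho92 the difference from WT varied between the 7 times, by an F test of the interaction (edgeR). The mutants differed from each other over 3 to 9 h in 3885 genes, by the direct contrast. These 3 results stood out because the effect of a mutation differed between times or between mutants. NDT80 showed the first kind. It stood at 9.93 ± 2.3 CPM in ime4 against 9.65 ± 0.901 in WT at 2 h, and at 1010 ± 459 against 6270 ± 229 CPM at 7 h (SD, n = 3). SPR3, a middle gene, showed the difference between mutants, at −2.72 (SE 0.25) in ime4 against pho92, or −2.06 without the libraries numbered 1.

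Each count was set against all 10 divisions of the 6 replicate series (or the 6 WT libraries) into 3 and 3, fitted to those libraries alone. In every comparison the true grouping gave the highest count, 1 of 10 divisions, and with 10 divisions the share cannot go under 0.05. Each other division mixed libraries of both true groups, so real differences between these groups widened its spread within groups. Low counts in the other divisions therefore do not show how many genes chance would call. For ime4 the true grouping called 20 genes at 0 h, 816 at 2 h, 1929 at 3 h, 2985 at 5 h, 4533 at 6 h, 4841 at 7 h, 4707 at 9 h, 4445 over 3 to 9 h and 5596 in the test over times, and the highest other count was 0 in each. For pho92 it called 998 at 0 h (highest other 1), 660 at 2 h (77), 967 at 3 h (0), 1916 at 5 h (0), 4096 at 6 h (0), 3608 at 7 h (0), 3272 at 9 h (0), 3425 over 3 to 9 h (5) and 5226 in the test over times (7). For ime4 against pho92 it called 3800, and the highest other count was 766, with pho92 series 3 grouped with ime4 series 1 and 2. In WT it called 3305 at 2 h against 0 h, and 4272, 4492 and 4623 at 3, 6 and 9 h against 2 h, with 0 as the highest other count.

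In pho92 the 48 genes between MAT and HMR on chromosome III had a median of −1.06 at 0 h, and the lowest median over 20 neighbouring genes was −1.13 on this chromosome (CTR86 to PAT1) and −0.29 on the next lowest. Scaling of the libraries was argued against by the 26 flanking genes, whose median was −0.04 at 0 h. Slower progress through meiosis was argued against by ime4, whose interval median was −0.05 over 3 to 9 h and 0.05 at 0 h. Whether 1 copy of the interval was missing from this diploid stays open. Of the 21 pho92 libraries 16 had an interval median within 0.25 of −1, under the bound of 19. The other 5, of 6 and 7 h, stood at −0.686 to −0.365. At 6 and 7 h the flanking genes of pho92 had medians of 0.41 and 0.09. In ime4 the interval stood at 0.38 and 0.45 at these times, and its flanking genes at 0.69 and 0.80. The level of this region relative to WT thus moved at 6 and 7 h, so a bound around −1 is less clear there. DNA copy number was not measured, and effects of the interval's genes, TUP1 among them, on other genes in pho92 stay open, as does an effect of PHO92 itself.

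The 1052 genes called between pho92 and WT at 0 h, where PHO92 was low in WT (10.9 CPM), were the other pattern weighed. The interval alone was argued against, since its genes were 3.8% of the calls. A single deviating library was argued against by the lowest count with 1 replicate series left out, 553, without WT replicate 2. Loss of PHO92, an indirect effect of the chromosome III interval and a difference between the cultures before transfer may each contribute and stay open.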

How the results depend on the processing

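The comparisons, lists, named-gene rule and alternatives were fixed before the data were examined, except the fits without libraries numbered 1 and without the genes between MAT and HMR, which were chosen after seeing the data. Where a value moved, the cause was not tested unless stated.

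Of 310 alternative counts for the 23 gene counts, 22 moved by over 1.5 times. With total counts only, RLE factors, no filter on low counts, the replicate block and the genes between MAT and HMR left out, all 23 counts stayed within that range, although the split into higher and lower moved with the scaling. Some genes called with both TMM and total counts changed sign. In ime4 these were 546 of 4008 at 6 h, 904 of 4230 at 7 h and 790 of 3799 over 3 to 9 h. In pho92 they were 287 of 3282 at 6 h, 227 of 2662 at 7 h and 86 of 2614 over 3 to 9 h. At 0, 2, 3, 5 and 9 h 0 did so in either mutant, and with RLE factors 0 did over 3 to 9 h. The direction with more called genes turned in 47 of 282 alternatives for 21 comparisons: in 8 with RLE factors, the same number with DESeq2 and with only the compared libraries, and 7 with total counts only. With only the compared libraries the 8 were WT at 9 h against 2 h (2276 higher and 2347 lower), ime4 at 0 h (0 and 1), 2 h (393 and 279), 3 h (1427 and 1232), 5 h (1715 and 1607) and 9 h (2183 and 2208), pho92 over 3 to 9 h (1513 and 1941) and ime4 against pho92 (1932 and 1885). The direction also turned with 1 replicate series left out for WT at 9 h against 2 h (2110 higher and 2235 lower without WT replicate 1, 1996 and 2162 without 2, 1973 and 2204 without 3), ime4 at 2 h (253 and 180 without WT replicate 1, 275 and 243 without ime4 replicate 1) and ime4 at 3 h (532 and 487 without WT replicate 2, 694 and 662 without 3, 737 and 699 without ime4 replicate 1, 526 and 520 without 2). The same held for pho92 at 5 h (725 and 861 without WT replicate 2, 851 and 936 without 3, 983 and 1001 without pho92 replicate 1) and ime4 over 3 to 9 h (2007 and 2229 without ime4 replicate 2). The 15 genes called in ime4 at 0 h became 26 with DESeq2, 1 in a fit to the compared libraries only (which has fewer residual degrees of freedom) and 205 without libraries numbered 1. In ime4 at 2 h 720 became 457 without libraries numbered 1. In pho92 a fit to the compared libraries only gave 166 in place of 720 at 2 h and 2215 in place of 1042 at 3 h.

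Leaving out each replicate series in turn gave 9 to 70 genes for ime4 at 0 h, 377 to 663 at 2 h and 1019 to 1581 at 3 h. For pho92 it gave 553 to 1326 at 0 h, 224 to 982 at 2 h, 395 to 1132 at 3 h and 1209 to 1984 at 5 h. The 16 of 126 counts beyond 1.5 times lay in these 7 comparisons. The other ranges were 2435 to 2623 for ime4 at 5 h, 4240 to 4464 at 6 h, 4610 to 4771 at 7 h, 4451 to 4615 at 9 h and 4215 to 4324 over 3 to 9 h. They were 3644 to 4208 for pho92 at 6 h, 3037 to 3933 at 7 h, 2879 to 3370 at 9 h and 2991 to 3695 over 3 to 9 h, and 3586 to 3951 for ime4 against pho92. In WT they were 2725 to 2948 at 2 h against 0 h, and 3171 to 3614, 4378 to 4488 and 4158 to 4345 at 3, 6 and 9 h against 2 h. The tests over times gave 5485 to 5565 in ime4 and 4854 to 5345 in pho92.

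With the replicate number as a block, the contrasts whose equal numbers correlated gave 3848 genes for WT at 3 h against 2 h, 1995 for pho92 at 5 h and 4141 at 6 h, and all 259 named results kept their direction and side of the threshold. The stage differences paired by number were −1.853 h for ime4 and −0.833 h for pho92, with an exact sign-flip p of 0.25 each, the smallest possible with 3 pairs.

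The 97 list calls became 3 with an estimated correlation and 194 with fry, which tests a list by itself and not against other genes. They were 103 with total counts only, 99 with the replicate block and 99 to 110 with a replicate series left out.

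The stage difference of ime4 kept its sign in all alternatives, from −2.03 to −1.683 h with a replicate series left out, −1.807 h with meiotic lists only, −1.933 h with Spearman correlation and −1.88 h with a WT span of 1 or total counts only. That of pho92 ran from −1.007 to −0.617 h, with −0.713 h for meiotic lists only. With 3 values per strain these tests cannot pass 0.05.

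Of 3382 alternative values for 259 results on named genes, 3303 kept direction and side of the threshold, 63 lost the call, 7 gained it and 9 changed sign. With total counts only IME1 changed sign in WT at 3 h against 2 h (0.03) and in ime4 at 5 h (0.20), as did PHO92 in ime4 at 7 h (1.04), HOS2 (0.10), COX13 (0.21) and PHO92 (0.33) in ime4 over 3 to 9 h, and HOS2 in pho92 over 3 to 9 h (0.13). That scaling moves the median of all genes, by 0.64 in ime4 and 0.31 in pho92 over 3 to 9 h. IME1 in ime4 at 3 h was 0.00 without WT replicate 1 (−0.37 to 0.00 over the series left out), and IME1 in pho92 over 3 to 9 h was −0.02 without pho92 replicate 3 (−0.02 to 0.22). Replicates differed by more than counting error over the sum of genes with more than 20 counts in a pair. That sum is weighted to high counts, and whether depth limits the calls of genes with few counts was not tested.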

Other observations

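All tests in this part were chosen after the result was seen.

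Some transcripts in ime4 stood outside the range of the whole WT course. In all 15 ime4 libraries of 3 to 9 h, 19 genes were above all 21 WT libraries and 3 genes, IME4, MAS1 and ACP1, were below, although with total counts only 25 were above and 1, IME4, below. If the 36 libraries were exchangeable, chance would give a gene such a separation with a share of 1.8e-10, but libraries of a strain and time are not independent. VPS73 had 115 to 504 CPM in ime4 against at most 92.2 in WT, and the protease gene YPS3 52.5 to 85.7 against at most 36.7. RDH54, which acts in recombination between homologues, had 249 to 492 CPM against at most 123, and RSR1, a bud-site selection GTPase gene, 93.3 to 169 against at most 73.6. RME1 had 25.7 to 52.9 CPM against at most 25.3. FUS3, the mating kinase gene, had 26.7 to 50.1 CPM in ime4 and 19.5 to 34.3 in pho92 against at most 18 in WT, the 1 gene above WT in both mutants, a separation lost in each mutant with total counts only. Of the genes given here YPS3 and IME4 kept it under that scaling. These genes were picked after their values were seen.

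In pho92, FUS3 and HRI1 were above all WT libraries, and PHO92, PAT1 and PTC6 were below. PAT1 (65.5 to 129 CPM against at least 149 in WT) and PTC6 (42 to 71.7 against at least 79.8) both lie between MAT and HMR. With total counts only PHO92 alone of these 5 genes kept the separation.

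A hypothesis was that these ime4 levels exceed what a delay along the WT course alone would give. In ime4 19 genes were above all WT libraries, which fell short of a first bound of 20. This count was replaced by a test of each pairing of an ime4 time with a WT time. Libraries simulated as delayed WT gave 0 genes in the count and in the test. Their means were interpolated between WT times and cannot exceed the highest WT mean, so these 0 values were set in advance and carry no weight. Above WT in all 35 pairings (largest one-sided p, BH adjusted, edgeR) were 6 genes with TMM, 3 with RLE factors and 5 with total counts only, or 26, 23 and 31 at an unadjusted p under 0.05, and 0 in the delayed libraries at either level. The measured counts go against a delay that passes only through the sampled WT levels, but the lowest, 3, was under the bound of 5 set for each scaling. WT levels between the sampled times are not known, so a delay alone stays open. YPS3 was called with each scaling (adjusted p = 0.00392, 0.00841 and 0.0151). Scaling of the libraries may also account for the pattern, since 10.5% of the 19 genes kept the separation with total counts only, although that scaling itself gave 25 such genes.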
